A study of Mus musculus with 8 samples.

How the data were processed

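RNA-seq and ATAC-seq libraries of sorted mouse LSK cells, 2 labelled WT and 2 labelled Hira KO per assay, were analysed from the files the authors deposited. Groups and replicate numbers came from the sample titles. RNA was amplified with a NuGEN kit and made into libraries with Illumina's Nextera XT kit, per the labels' protocols; neither the labels nor the files say that strand was kept, so a gene and an antisense partner cannot be told apart. The submitters' processing notes name Trim Galore 0.4.5, Bowtie2 2.2.9, MACS2 2.1.1, bedtools, DESeq2, STAR 2.5.3a, HTSeq and RSEM 1.3.0 and the build GRCm38, without saying which step each served.

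Each RNA file held the authors' expected count, effective length and TPM per gene in RSEM's layout, per the file headers. The expected counts deposited by the authors are estimates that need not be whole and carry no normalization. The TPM values deposited by the authors are scaled to the same total in each library. Each ATAC file was a narrowPeak list called per library, with the authors' fold enrichment (a ratio to the caller's background) and the authors' -log10 p-value and -log10 q-value per peak. These peak values were used to rank or filter peaks within a list. At named regions they are also printed per library, without a test between lists. How the transposase offset was treated is not given in the sources used here. No read depth comes with the peak lists.

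Gene IDs were matched to symbols for 45143 of 45706 genes; the other 563 kept their IDs. Positions and biotypes came from a RefSeq table of GRCm38.p6, matched by symbol. That table gives no strand, so the planned distance to the transcription start was replaced by the distance to the gene body (10 kb, with 2 kb and 50 kb as alternatives). The planned motif test was not run, because no genome sequence was used here.

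Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test with robust dispersion, genotype as the only term), which left 16258 genes; p-values were adjusted by Benjamini-Hochberg and called below 0.05. CPM are counts divided by the TMM-scaled library size, on the usual scale. The biological coefficient of variation was 27.8%. SEs and 95% intervals were derived from the quasi-likelihood F statistic and its degrees of freedom. Folds against a group without counts were taken against a floor of 3 counts per library. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, 2-sided, lists of at least 5 tested genes), with camera at an estimated correlation and fry beside it. Of 30 lists fixed before the data were examined 29 could be tested; the list of sex-linked genes had too few. Libraries of the same group differed by more than sampling noise, with chi-square values per gene of 55.2 between the labelled WT libraries and 76.8 between the labelled Hira KO libraries. The depth of 16.6 to 19.8 M counts per library limits genes of low count most.

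Genes were named by a rule fixed before the data were examined: Hira first, then the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose groups did not overlap and whose average log2 CPM was at least 3, leaving out unnamed gene models, pseudogenes and mitochondrial genes, and up to 4 members of each list by p-value. The 3 regions per group with the highest fold enrichment were named by the lower of the 2 libraries' percentile ranks.

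Peaks that shared an interval were counted as 1, and the mitochondrial interval of each list was left out. Peaks of the 4 lists that overlapped by at least 1 bp were merged. A region belonged to a group when both its libraries and neither of the others called it. Shares of genes near such regions were compared with 2-sided Fisher's exact tests in scipy 1.17.1 among 13493 tested genes with any region nearby. Tests of list genes against regions, and tables by expression level, were chosen after the data had been seen.

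The edgeR step was tested on simulated counts for the comparison of labelled Hira KO with labelled WT, drawn from the real means, library sizes and dispersions (15739 genes in the fit). Of 50 genes changed 1.5-fold 4% were called, of 50 changed 2-fold 38%, of 50 changed 4-fold 88% and of 50 changed 8-fold 100%. These genes were drawn among those with a mean of at least 4 CPM, so the shares do not cover genes of lower count. Of 15500 unchanged genes 27 were called, 18.8% of the 144 calls, above the nominal share. Camera called 2 of 29 simulated lists, among them the 1 list shifted 1.5-fold, the G2 and mitosis genes. Simulated genes were drawn independently, whereas the correlation estimated for that list in the real data was 0.611. The simulation therefore does not measure how often camera calls unchanged lists of correlated genes. The merging of peaks was checked on made-up lists and returned the 40 and 70 group-specific regions put in.

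Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors and upper-quartile factors in edgeR, no low-count filter, a stricter one (CPM of at least 5 in 2 libraries), limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 2 libraries, each library left out, the replicate number as a block, an offset for gene length alone and with that block, and protein-coding genes only. For peaks they were a -log10 q of at least 5, equal numbers of peaks per list, the strongest 20000 peaks, an overlap of 50% of the shorter peak, and each library left out. Added after the data were seen were fits without mitochondrially encoded, immunoglobulin or X and Y genes, and an odds ratio over 5 strata of genes by the number of nearby regions.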

Results

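RNA sequencing and ATAC-seq, which maps open chromatin by the insertion of a transposase, were measured in LSK cells sorted from the bone marrow of C57BL/6 mice. LSK cells are lineage-negative, Sca1-positive and Kit-positive, a gate that holds the haematopoietic stem cells (HSC) and the multipotent progenitors. The mice were wild type (WT) or carried a conditional knockout (KO) of Hira, which encodes a histone chaperone that deposits the histone variant H3.3 outside replication. Each assay had 2 libraries labelled WT and 2 labelled Hira KO. The RNA libraries held 16.6 and 19.8 M expected counts (labelled WT replicates 1 and 2) and 17.5 and 19.4 M (labelled Hira KO replicates 1 and 2). Mitochondrially encoded genes took 40.8%, 51.7%, 42.9% and 53.1% of these counts in the same order, with 95% Wilson bounds within 0.0237 percentage points of each share. Most of this was mitochondrial ribosomal RNA, since mt-Rnr1 and mt-Rnr2 took 36.7%, 46.4%, 38.6% and 48.5% of all counts. The 4 peak lists held 79565, 63422, 92839 and 73715 peaks, in the same order of groups and replicates, and no read totals, so the depth behind them was unknown. The labels do not say which libraries came from separate mice. Sex-linked transcripts and peaks, given below, differed between the labelled WT RNA libraries and between ATAC replicates 1 and 2 of each group, so these did not share a single mouse. For the labelled Hira KO RNA libraries, both female-like, the source is unknown, and p-values describe the spread between these libraries.

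Hira itself was lower in the libraries labelled WT. It stood at 16.5 and 17.2 CPM (counts scaled to a common library size) in labelled WT and at 24.4 and 23.3 CPM in labelled Hira KO, a log2 fold change of 0.50 (SE 0.19, 95% interval 0.05 to 0.95, labelled Hira KO over labelled WT, n = 2 and 2). The edgeR adjusted p over all genes was 0.180. The direction went against the titles, and all 8 deposited file names also carried the opposite genotype from their titles. Libraries are therefore called labelled WT and labelled Hira KO throughout, and every direction given here depends on those labels. A count over the whole gene can keep reads from exons outside the deleted part, so it checks the labels only in part. At the Hira locus (chromosome 16, 18876750 to 18970309, GRCm38) the region at 18876178 to 18878384 was called in all 4 ATAC libraries. It covers the low-coordinate boundary of the gene, and without strand in the annotation it was not determined whether transcription starts or ends there. Its fold enrichments by the authors' caller were 80.2 and 53.5 in labelled WT and 70.4 and 54.6 in labelled Hira KO. The region at 18896391 to 18896955, within the gene, was also called in all 4, with 28.1 and 21.3 in labelled WT and 7.46 and 18.5 in labelled Hira KO. No region at Hira was called in both libraries of one group and in neither of the other.

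The first comparison asked which transcripts differed between LSK cells of the 2 genotypes. In labelled Hira KO, 11 of 50 HSC genes, 7 of 53 interferon-stimulated genes and 23 of 97 immunoglobulin genes (Jchain included) passed upward, and 3 of 39 mitotic genes and 1 of 31 erythroid genes downward. The lists of HSC, interferon-stimulated, mitotic, replication and erythroid genes passed camera at its preset correlation but not with an estimated correlation. There the adjusted p was 0.485 for each, a value they share through the adjustment (unadjusted values are given below). Immunoglobulin genes were not tested as a list. edgeR's quasi-likelihood test called 214 genes higher and 78 lower in labelled Hira KO among 16258 tested (Benjamini-Hochberg adjusted p below 0.05), and 3703 genes had an unadjusted p below 0.05. In all 292 called genes the CPM of the groups did not overlap, against 56.1% of all tested genes and 33.3% by chance. Among called genes with an average log2 CPM of at least 3, the tight junction gene Tjp1 fell by the largest fold, from 63.3 ± 7.34 to 6.88 ± 2.07 CPM (mean ± SD, n = 2 each; log2 fold change -3.20, SE 0.25, edgeR adjusted p = 0.00842), and 4 ATAC regions within 10 kb of it were called only in the labelled WT pair. The fibrillar collagen gene Col5a1 fell from 29.1 ± 3.23 to 3.27 ± 1.82 CPM (log2 fold change -3.14), with 3 such regions. None of the decreased genes named next had such a region, and Pkd1l3 had 1 called only in the labelled Hira KO pair. The scavenger receptor gene Stab2 (log2 fold change -2.42), the proteoglycan gene Gpc1 (-2.08), the sulfatase gene Sulf2 (-1.93), the lysosomal thiol reductase gene Ifi30 (-1.87), the monocyte gene Ly6c2 (-1.83) and the inhibitory Fc receptor gene Fcgr2b (-1.78) also fell, as did Pkd1l3 (-2.62), Parm1 (-1.78), Gstm5 (-1.77) and Pik3r2 (-1.71). Among called genes at that expression level, outside the immunoglobulin genes and Jchain, the largest increases were in the cation channel gene Trpc6 (2.08 ± 1.47 to 17.7 ± 5.08 CPM, log2 fold change 3.08), Abcg3 (2.95), Tnip3 (2.78) and Bpifc (2.72), all past edgeR's threshold. By limma on log2(TPM + 1), where the pseudocount shrinks low values, the log2 fold change was 1.94 for Abcg3, -1.80 for Col5a1, -1.67 for Pkd1l3 and -1.18 for Parm1, and for genes named below -1.30 for Cdh5, 0.97 for Ddx58 and 1.49 for Rian. On log2(TPM + 0.1) it was -2.02 for Ccnd1 and 2.95 for Rian. DESeq2 called 918 higher and 570 lower, limma on log2(TPM + 1) called 374 and 222, and with 1 library left out edgeR's calls ran from 3 and 1 (without labelled WT replicate 1) and 1 and 1 (without labelled WT replicate 2) to 665 and 525 (without labelled Hira KO replicate 2) and 1657 and 1888 (without labelled Hira KO replicate 1). Labelled WT replicate 2 was male-like, with 906 counts of the Y-linked gene Ddx3y and 1470 of Xist, against 1 or 2 of Ddx3y and 169234 to 232764 of Xist in the other 3, so only female-like libraries remain without it. The medians of the HSC, immediate-early, erythroid and G2 and mitosis lists described below were then 0.99, 2.07, -1.50 and -0.55, and all 4 passed camera at the preset correlation.

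Among 29 gene lists fixed before the data were examined and large enough to test, 17 passed camera (adjusted p below 0.05, preset inter-gene correlation 0.01). None passed with an estimated correlation, where the adjusted p was 0.485 for HSC, interferon-stimulated, immediate-early, G2 and mitosis, S-phase, erythroid and Hox genes. The unadjusted camera p was then 0.0201 (HSC), 0.0498 (Hox), 0.0952 (interferon-stimulated), 0.137 (S-phase), 0.189 (erythroid), 0.196 (G2 and mitosis) and 0.218 (immediate-early). The shared 0.485 comes from the adjustment, and the correlation was estimated from only 4 libraries. None passed the directional fry test, whose lowest adjusted p was 0.0839, for HSC, progenitor and Hox genes. HSC genes had a median log2 fold change of 0.88, 46 of 50 lay above 0, and 11 passed upward and 0 downward over all genes tested (29 and 1 adjusted over the list alone; camera adjusted p = 9.1e-17, 0.485 with an estimated correlation). The HSC transcription factor gene Hlf rose from 75.8 ± 14.0 to 305 ± 68.6 CPM (log2 fold change 2.01, SE 0.21, edgeR adjusted p = 0.0180), Meis1 from 74.4 ± 6.23 to 223 ± 24.7 CPM (1.58, SE 0.16) and the Tie2 ligand gene Angpt1 from 82.8 ± 3.15 to 268 ± 30.2 CPM (1.70, SE 0.15). Hox cluster and cofactor genes had a median of 0.95, with 2 of 22 past the threshold upward, Meis1 and Hoxa9 (1.17), and 0 downward (7 and 2 adjusted over the list alone), and a median of 0.62 on log2(TPM + 1). In the multipotent and lymphoid-primed progenitor list (median 0.40, 3 of 23 past the threshold, all upward; 9 up and 2 down adjusted over the list alone) the cytokine receptor gene Flt3 (1.42), Cd27 (0.88) and the sphingosine phosphate transporter gene Spns2 (0.94) rose. That list's adjusted p was 0.0302 by camera and 0.485 with an estimated correlation. By camera it was 0.0792 without labelled WT replicate 1, 0.175 without labelled WT replicate 2 and 0.117 without labelled Hira KO replicate 1. It was 0.0681 with the replicate number as a block, 0.0660 with the length trend also removed, and 0.206 and 0.178 by limma on log2(TPM + 1) and log2(TPM + 0.1), where the median was 0.18 and 0.19.

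Interferon-stimulated genes had a median of 0.67 (46 of 53 above 0; 7 past the threshold upward and 0 downward over all genes, 24 and 0 adjusted over the list alone; camera adjusted p = 3.8e-12, 0.485 with an estimated correlation). Ifi44 went from 8.33 ± 0.642 to 49.6 ± 4.01 CPM (log2 fold change 2.57, SE 0.19, edgeR adjusted p = 0.00798). The double-stranded RNA sensor genes Oas2 (4.59-fold higher) and Ddx58 (log2 fold change 1.49) and the antiviral gene Oasl2 (1.88) followed. Immediate-early genes, which answer signals and cell handling within minutes, had the largest median, 2.22, with 27 of 29 above 0. Ier2 (2.43), Ier5 (2.16) and Ppp1r15a (2.15) passed, and none passed downward (11 up and 0 down adjusted over the list alone; camera adjusted p = 4.0e-14, 0.485 with an estimated correlation, which was 0.859). Labelled Hira KO replicate 2 stood higher in them than replicate 1, with medians of 2.65 and 3.12 over the labelled WT libraries against 1.31 and 1.87. That library also had 6 counts of AY036118, against 86174 to 108841 in the other 3, and the lowest of the libraries' highest correlations with the other group (0.893). The list of CDK inhibitors and quiescence genes had a median of 0.61 (camera adjusted p = 0.0223, 0.570 with an estimated correlation), with the antiproliferative gene Btg1 higher (1.84) and the cyclin gene Ccnd1 lower (-1.26). It had 4 members up and 4 down adjusted over the list alone, and its camera adjusted p was 0.124 without labelled WT replicate 2. Its median was 0.31 without labelled Hira KO replicate 2, 0.36 with no low-count filter, and 0.26 and 0.28 on log2(TPM + 1) and log2(TPM + 0.1).

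All 39 G2 and mitosis genes lay below 0 (median -0.67, camera adjusted p = 1.7e-14, 0.485 with an estimated correlation). Over all genes 3 passed, all downward, namely the chromosomal passenger genes Incenp (68.5 ± 5.52 to 35.1 ± 2.97 CPM, log2 fold change -0.96) and Aurkb (-0.97) and the spindle checkpoint gene Bub1b (-1.02), and 30 passed adjusted over the list alone. Of 50 S-phase and DNA replication genes 49 lay below 0 (median -0.54, camera adjusted p = 9.6e-12, 0.485 with an estimated correlation). None passed over all genes and 21 did, all downward, adjusted over the list alone. The ribonucleotide reductase gene Rrm2 had a log2 fold change of -1.40 (edgeR adjusted p = 0.0563), Uhrf1 of -0.89 and the helicase subunit gene Mcm3 of -0.65. DNA damage repair genes had a median of -0.38 (camera adjusted p = 0.00135, 0.559 with an estimated correlation), with 0 of 34 past the threshold both over all genes and over the list alone, and a median of -0.21 without labelled Hira KO replicate 2. Replication-dependent histone genes had a median of -0.67 over 54 genes (camera adjusted p = 0.00135, 0.729 with an estimated correlation), with Hist2h3c2 lower (-2.88) and Hist1h2bc higher (1.59), and 3 up and 3 down adjusted over the list alone. Reads of these near-identical genes can be split between copies, and without labelled Hira KO replicate 2 the median was -0.16 and the camera adjusted p 0.871. Without replicate 1 of that group the median was -1.55. The HIRA complex and histone chaperone list had a median of -0.25 (34 genes, camera adjusted p = 0.0119, 0.485 with an estimated correlation), and its only called member, the chromatin remodeller gene Chd2, rose (0.98; 1 up and 1 down adjusted over the list alone). The list's camera adjusted p was 0.0676 without labelled Hira KO replicate 2, 0.0673 with the stricter low-count filter and 0.0525 on log2(TPM + 1).

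Erythroid, granulocyte, mast cell, dendritic cell and stromal lists passed camera downward. Erythroid genes had the lowest median, -1.43 (26 of 31 below 0, camera adjusted p = 4.7e-09, 0.485 with an estimated correlation), with Tspo2, a translocator protein gene of erythroid cells, past the threshold over all genes (-2.24) and 3 members adjusted over the list alone. The transferrin receptor gene Tfrc had a log2 fold change of -1.29 (edgeR adjusted p = 0.0757). The median of the erythroid list was -0.98 without labelled Hira KO replicate 2 and -2.51 without replicate 1. Granulocyte and monocyte genes had a median of -0.72 (camera adjusted p = 7.0e-05, 0.485 with an estimated correlation). Lcn2 (-1.31) and Ly6c2 fell while the cytokine receptor gene Csf3r rose (1.04), with 2 up and 12 down adjusted over the list alone. The median of that list was -0.39 without labelled WT replicate 1. Mast cell, basophil and eosinophil genes had a median of -1.08 (camera adjusted p = 0.00144), with 0 of 14 past the threshold over all genes and 1 up and 6 down adjusted over the list alone, and a median of -0.51 without labelled WT replicate 1 and -0.63 with the stricter filter. The dendritic cell and MHC class II list (median -0.72, camera adjusted p = 0.0292) had 2 members past the threshold, Flt3 and Runx2 (0.79), and both rose, with 2 up and 4 down adjusted over the list alone. Its camera adjusted p was 0.0574 without labelled WT replicate 1 and 0.211 without labelled Hira KO replicate 1, and 0.128 with the stricter filter. Stromal and endothelial genes (median -0.63, camera adjusted p = 0.00812) fell in Cdh5, the endothelial cadherin gene (-2.94), and Stab2, with 1 up and 6 down adjusted over the list alone, and the camera adjusted p was 0.217 without labelled Hira KO replicate 1. The median of the stromal list was -1.12 without that library and -1.67 without replicate 2 of the same group. With the stricter filter it was 0.25, the opposite sign (camera adjusted p = 0.211), and on log2(TPM + 1) and log2(TPM + 0.1) it was -0.19 and -0.28 (0.0599 and 0.0990). With an estimated correlation the adjusted p of the mast cell, dendritic cell and stromal lists was 0.485. Heat shock and unfolded protein response genes had a median of -0.30 (camera adjusted p = 0.0226, 0.559 with an estimated correlation). The endoplasmic reticulum chaperone gene Hyou1 (-1.11) and the mitochondrial chaperonin gene Hspd1 (-0.93) fell and Dnajb9 rose (1.59), with 1 up and 8 down adjusted over the list alone. Without labelled WT replicate 1 the median of that list was -0.09 and its camera adjusted p 0.22, and without labelled Hira KO replicate 1 the adjusted p was 0.805. It was 0.104 with the stricter filter and 0.206 and 0.180 on the TPM scales.

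**Figure D1:**
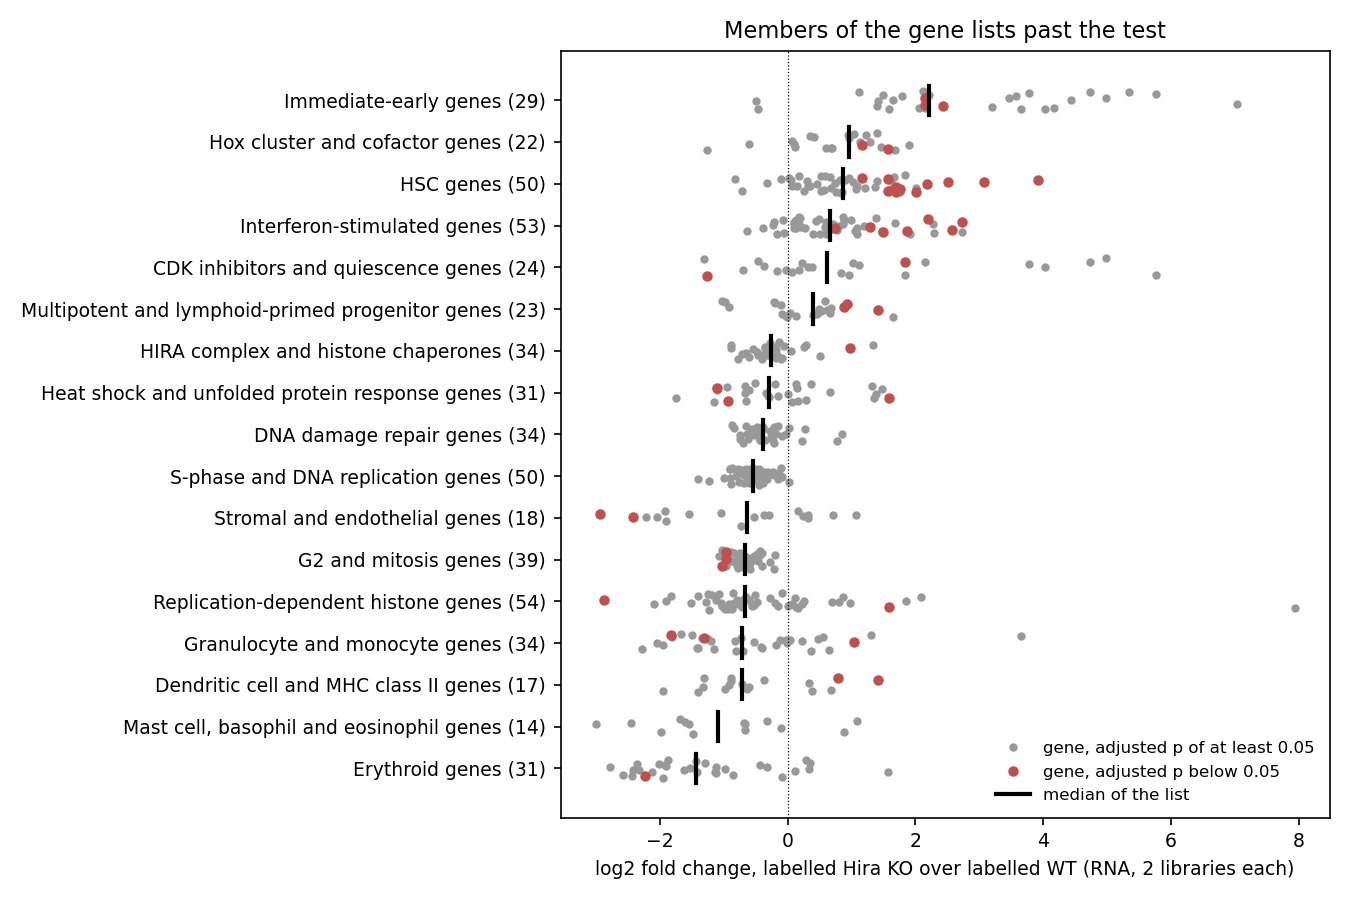
Each point is a gene of a list that passed camera, at its log2 fold change (labelled Hira KO over labelled WT, 2 libraries each, horizontal axis), with the number of tested genes after the list's name. Red points passed edgeR's threshold over all genes and black bars are list medians, from 2.22 for immediate-early genes to -1.43 for erythroid genes.

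The other 12 tested lists did not pass camera. Their median log2 fold changes were -0.05 for megakaryocyte and platelet genes (mean 0.27), -0.51 for B cell genes, -0.09 for T and NK cell genes, -0.13 for macrophage genes, -0.14 for p53 targets (mean 0.06), 0.16 for ETS, RUNX and GATA factors, 0.82 for imprinted genes, 0.19 for the fetal HSC program (camera direction down), 0.05 for ribosomal proteins, 0.03 for mitochondrially encoded proteins, 0.14 for apoptosis genes and 0.35 for Wnt, Notch and TGF-beta targets (1.10 on log2(TPM + 0.1)). Imprinted genes had a median of 0.09 without labelled Hira KO replicate 2, 0.32 without labelled WT replicate 1 and 0.18 with the stricter filter. They passed camera without labelled WT replicate 2 (1.11, adjusted p = 0.0110), with no filter (0.0435) and with the replicate block (0.0382). B cell genes passed downward without labelled WT replicate 2 (camera adjusted p = 0.0370), with no filter (0.0115), with protein-coding genes alone (0.00171) and without immunoglobulin genes (median -0.77, 6.8e-04). Without labelled WT replicate 2 the macrophage list (-0.32, 0.0280) and the mitochondrially encoded list (0.39, 0.00237) passed, as did Wnt, Notch and TGF-beta targets without labelled Hira KO replicate 1 (1.01, 0.00459). Single members passed in some of these 12 lists. The multimerin gene Mmrn1 (1.63), the coreceptor gene Cd4 (1.77), the p53 target Sesn1 (0.96), the imprinted RNA gene Rian (4.54) and the survival gene Mcl1 (1.15) were higher, and the p53 target Zmat3 was lower (-1.58).

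Immunoglobulin genes made up a separate block of increases. They and Jchain took 0.0803% of counts in labelled WT replicate 1 (95% Wilson interval 0.0789 to 0.0816) and 0.0594% in replicate 2 (0.0584 to 0.0605). In labelled Hira KO they took 0.625% in replicate 1 (0.621 to 0.628) and 0.299% in replicate 2 (0.296 to 0.301); these intervals cover counting error only. Of 97 tested genes 80 had a log2 fold change above 1, and 23 of the 214 higher genes were of this class. The kappa constant gene Igkc stood at 97.1 and 97.2 CPM in labelled WT and at 1297 and 811 CPM in labelled Hira KO (log2 fold change 3.44, edgeR adjusted p = 0.00798). Ighm rose from 420 ± 13.1 to 2290 ± 1042 CPM (2.45), Jchain from 10.1 ± 4.18 to 159 ± 47.4 CPM (3.97), Ighg2b by 3.46 and Iglc1 by 4.75 on the log2 scale. Igkv5-39 had no count in either labelled WT library and 17.4 ± 6.09 CPM in labelled Hira KO, at least 106-fold higher against a floor of 3 counts per library. The variable genes Ighv11-2 and Ighv1-81 reached 21.9 ± 11.3 and 25.6 ± 13.3 CPM and Ighg2c 21.5 ± 0.206 CPM from below 0.4 CPM in labelled WT. Reads of variable genes can be shared between paralogs. The surrogate light chain gene Igll1 fell (-1.21).

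**Figure D2:**
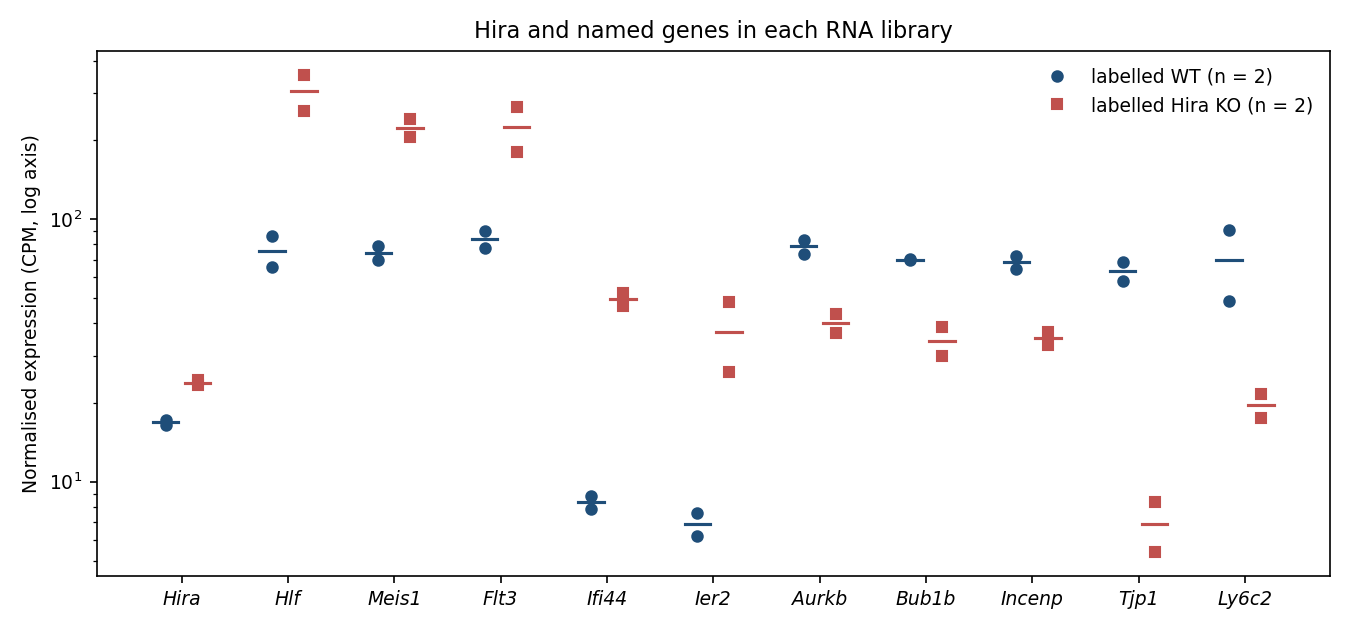
Normalised expression (CPM, log axis) of Hira and 10 named genes in each RNA library; circles are labelled WT, squares labelled Hira KO and bars the means of 2 libraries. Hira stands at 16.5 and 17.2 CPM in labelled WT and at 24.4 and 23.3 CPM in labelled Hira KO.

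The second comparison asked where open chromatin differed. Regions called only in the labelled WT pair lay within Cops6 and Ddx5, among others, and regions called only in the labelled Hira KO pair within 2610307P16Rik and near Jph3. The 4 lists merged into 112479 regions, of which 45779 were called in all 4 libraries. Regions called in both labelled WT libraries and neither labelled Hira KO library numbered 3118, and regions called only in the labelled Hira KO pair 6341. The strongest of the labelled WT regions by the authors' fold enrichment (GRCm38) were at chromosome 5, 138162829 to 138164025, within the signalosome subunit gene Cops6 and 558 bp from the helicase gene Mcm7 (fold enrichment 21.4 and 24.6). Next were chromosome 11, 106781626 to 106782623, within the RNA helicase gene Ddx5 (20.8 and 26.3), and chromosome 4, 156245723 to 156247650, overlapping Noc2l and Samd11 (20.01 and 27.9). The strongest labelled Hira KO regions were at chromosome 13, 28502084 to 28502557, within the unnamed gene model 2610307P16Rik (17.9 and 14.1), whose transcripts were higher (log2 fold change 1.33, edgeR adjusted p = 0.0347). Next were chromosome 8, 121792069 to 121792560, outside genes and 986 bp from Jph3 (18.6 and 13.04), and chromosome 5, 105356375 to 105356754, outside genes and 9899 bp from Gbp11 (11.0 and 12.4). The annotation used gives gene bodies only, so exon or intron was not determined. Splitting the same libraries by replicate number gave 6169 regions only in the replicate 1 pair and 756 only in the replicate 2 pair, and the crossed split gave 1380 and 461; with 3 possible splits no p below 0.05 could be reached. With the same number of peaks taken from each list the counts were 4400 and 3818, and without labelled WT replicate 2 they were 13049 and 8123, so the excess of labelled Hira KO regions turned in both. They were 5680 and 13221 without labelled WT replicate 1, 5928 and 10728 without labelled Hira KO replicate 1, and 5139 and 25745 without labelled Hira KO replicate 2.

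The replicate numbers of the ATAC libraries also separated by sex. Peaks at the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d numbered 0 in replicate 1 of both groups, 6 in labelled WT replicate 2 and 7 in labelled Hira KO replicate 2. The Xist region on chromosome X at 103481160 to 103482508 was called in replicate 1 of both groups, with fold enrichments of 22.1 and 17.7, and in neither replicate 2. Within the replicate 1 pair 16179 regions were called only in labelled WT and 27872 only in labelled Hira KO, and within the replicate 2 pair 8373 and 18651.

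The third comparison asked whether genes that changed in expression lay near regions called in one group alone. Genes higher in labelled Hira KO did. A region found only in the labelled Hira KO pair lay within 10 kb of the gene body for 71 of 181 higher genes (39.2%) and for 3079 of 13240 genes not called (23.3%), an odds ratio of 2.13 (2-sided Fisher's exact test, adjusted p = 8.5e-06 over 4 tests). Among the higher genes, the NF-kappaB regulator gene Tnip3 had 5 such regions, Runx2 5, Meis1 3 and Angpt1 2. Regions found only in the labelled WT pair were rarer near higher genes (18 of 181, 9.94%, against 17.8%; odds ratio 0.51, Fisher's exact adjusted p = 0.00871). Genes lower in labelled Hira KO had labelled WT regions nearby in 19 of 72 cases (26.4%, odds ratio 1.66) and labelled Hira KO regions in 10 of 72 (13.9% against 23.3%, odds ratio 0.53), both with a Fisher's exact adjusted p of 0.0680. Labelled Hira KO replicate 2 was female-like in RNA (171024 counts of Xist, 1 of Ddx3y) and had 7 peaks at Y-linked genes in ATAC, so its libraries did not share a single mouse. Genes are not independent replicates, so these tests describe these regions and genes and not mice. With the strongest 20000 peaks of each list the odds ratio of labelled Hira KO regions near higher genes was 1.89 (Fisher's exact adjusted p = 0.117), and without labelled Hira KO replicate 2 it was 4.08. That of labelled WT regions near higher genes was 0.82 with equal numbers of peaks (adjusted p = 0.426) and 0.79 without labelled WT replicate 2 (0.178). For lower genes, the odds ratio of labelled WT regions was 1.87 without labelled WT replicate 1 (adjusted p = 0.0154) and 1.86 without labelled Hira KO replicate 2 (0.0188). With the strongest peaks it was 1.02 (0.870). The odds ratio of labelled Hira KO regions near lower genes was 0.52 without labelled Hira KO replicate 1 (adjusted p = 0.0249), 0.89 at a stricter q (0.769) and 0.24 with the strongest peaks (0.373).

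**Figure D3:**
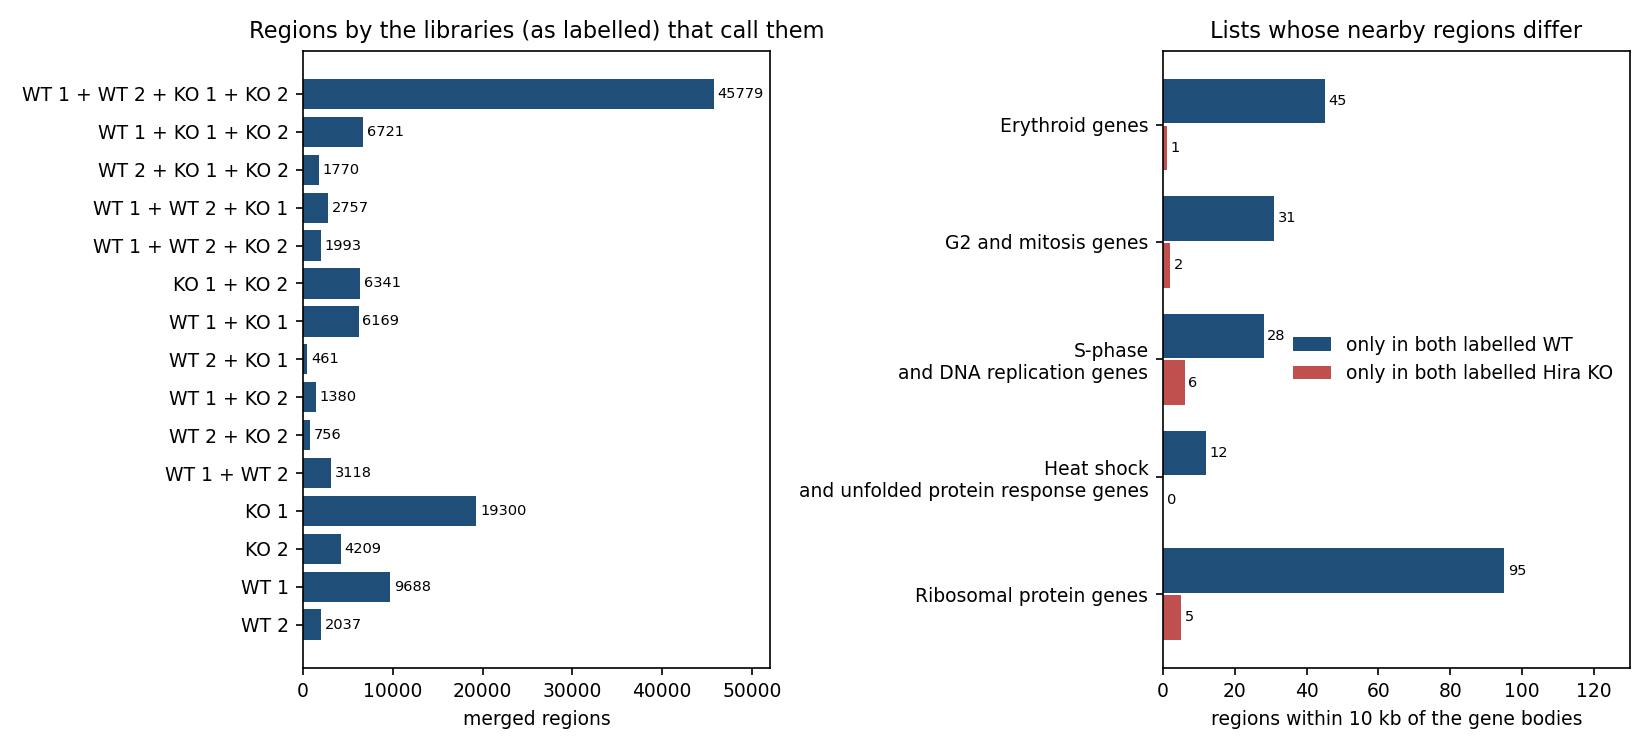
Left, merged ATAC regions by the set of libraries (as labelled) that called them, as bars from 0, with 3118 regions only in the labelled WT pair and 6341 only in the labelled Hira KO pair. Right, regions of these 2 kinds within 10 kb of the genes of each list for which they differed, such as 95 and 5 at ribosomal protein genes.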

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

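Fits without mitochondrially encoded, immunoglobulin or X and Y genes, and the odds ratio over 5 strata, were chosen after seeing the data; the cause of the changes below was not tested unless stated. Hira kept its direction in all 18 alternatives (log2 fold change 0.29 to 0.55; 0.45 to 0.53 with 1 library left out) and never passed the threshold. Of 2378 values of named genes under the alternatives 2372 kept their direction, 170 no longer passed and 270 newly did; of 519 list values 27 turned, 24 no longer passed camera and 10 newly did, and 14 to 19 lists passed with 1 library left out.

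Against 214 genes higher and 78 lower, there were 1206 and 1017 with no low-count filter, 411 and 180 with protein-coding genes alone, 918 and 570 by DESeq2, 374 and 222 by limma on log2(TPM + 1), and 195 lower on log2(TPM + 0.1). Of the calls 73.3% were higher in edgeR, 61.7% in DESeq2 and 62.8% and 62.1% by limma on the 2 TPM scales. With the replicate number as a block there were 368 and 169, and 431 and 208 with the length trend also removed. Same-numbered libraries hardly deviated together gene by gene (correlation of deviations 0.061), and the numbers were not taken to pair the libraries. The mitochondrial share did go with the number, at 40.8% and 42.9% in replicates 1 and 51.7% and 53.1% in replicates 2. The TMM factors (1.14 and 1.11 against 0.922 and 0.861) were lower where that share was higher, so they are not a separate sign. A batch shared by number is therefore not excluded. Leaving out 1 library gave 1 to 1657 higher and 1 to 1888 lower genes; the lone library left in a group was then assumed to vary like the others.

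By its median, the stromal and endothelial list, which had passed, turned from -0.63 to 0.25 with the stricter filter, while its test stayed downward. By the median p53 targets (-0.14) turned to 0.13 with that filter and 0.0508 without labelled WT replicate 1, and medians near 0 of the megakaryocyte, fetal HSC and mitochondrially encoded lists changed sign in several settings. By the sign of the list test or of the gene's fold change, turns fell on results that had not passed. Medians were, for apoptosis genes (0.14), 0.14 with DESeq2 size factors, 0.18 with upper-quartile factors, 0.14 with no filter, 0.0157 with the block, 0.0301 with block and length, and -0.0871 and -0.142 on TPM + 1 and TPM + 0.1. For ribosomal proteins (0.05) they were 0.0223 with no filter and -0.0632 and -0.0637 on TPM + 1 and TPM + 0.1, for Wnt, Notch and TGF-beta targets 0.32 with no filter, for T and NK cell genes 0.16 with the stricter filter, and for the fetal HSC program 0.40 with protein-coding genes and 0.35 without X and Y genes. With 1 library left out, medians ran from -0.0894 to 0.20 (apoptosis), -0.0396 to 0.10 (ribosomal), -0.39 to 1.01 (Wnt, Notch and TGF-beta), -0.75 to 0.34 (T and NK), -0.32 to 0.33 (macrophage), -0.26 to 0.39 (mitochondrially encoded), -0.23 to 0.37 (megakaryocyte), -0.81 to -0.51 (B cell) and -0.0427 to 0.23 (fetal HSC). Fold changes ran from -0.67 to 0.0652 (mt-Nd1), -5.29 to 0.40 (Uty), -1.81 to 0.46 (Kdm5d), -0.00955 to 0.94 (Tsix), -0.10 to 0.60 (mt-Co2) and -0.0551 to 0.79 (mt-Atp8). Reads of Uty and Kdm5d can be shared with their X homologs.

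For regions, equal numbers of peaks gave 3818 only in labelled Hira KO, and the strongest 20000 peaks 1193 only in labelled WT and 998 only in labelled Hira KO, where fewer peaks were used. Leaving out 1 library gave 5139 to 13049 and 8123 to 25745. The odds ratio of labelled WT regions near higher genes no longer passed at a stricter q (0.66), with equal numbers (0.82), the strongest peaks (0.87) or within 2 kb (0.54), and that of labelled Hira KO regions near higher genes did not with the strongest peaks (1.89). That of labelled Hira KO regions near lower genes passed with 50% overlap (0.47) and over the strata (0.43). With 1 library left out the odds ratios were 1.79 to 4.08 (labelled Hira KO regions, higher genes), 0.52 to 0.97 (labelled Hira KO, lower), 0.48 to 0.79 (labelled WT, higher) and 1.28 to 1.87 (labelled WT, lower). The planned motif test was not run, for lack of a genome sequence. Genes of low count are limited most by depth, and peak lists carry no depth.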

Other observations

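Tests on regions near gene lists, on exchanged titles, on the sex of labelled WT replicate 2, on a single mislabelled library and on B cell RNA were chosen only after the result was seen. How the mislabelling, scaling, plasma cell, B cell and left-out-library values were read against their bounds was also settled after those values had been seen. Regions called only in the labelled WT pair were more frequent than regions called only in the labelled Hira KO pair near 5 lists. They numbered 95 against 5 at ribosomal protein genes (Fisher's exact adjusted p = 1.966e-38 over the lists), 45 against 1 at erythroid genes (7.506e-20), 31 against 2 at G2 and mitosis genes (2.466e-12), 28 against 6 at S-phase genes (2.944e-08) and 12 against 0 at heat shock genes (9.411e-06). The anion exchanger gene Slc4a1 had 9 labelled WT regions and no labelled Hira KO region, the ankyrin gene Ank1 6 and 0, Mki67 6 and 0 and Aurka 5 and 0. Near HSC genes there were 26 and 28, which is 0.834% of labelled WT and 0.442% of labelled Hira KO regions. The odds ratio was 0.527 (labelled Hira KO over labelled WT, Fisher's exact adjusted p = 0.0731). With the same number of peaks per list the counts were 86 against 0 at ribosomal, 47 against 1 at erythroid and 23 against 0 at G2 and mitosis genes. Within the replicate 1 pair they were 179 against 33 (ribosomal), 124 against 9 (erythroid), 83 against 24 (G2 and mitosis), 99 against 54 (S-phase) and 62 against 25 (heat shock). Within the replicate 2 pair they were 164 against 23, 77 against 16, 66 against 20, 62 against 39 and 23 against 25, the last with an odds ratio of 0.487 among more labelled Hira KO regions in all (Fisher's exact adjusted p = 0.0179). The regions of each pair include all those of the main count, and only the lists that differed there were recounted. The pair counts are therefore not independent of the main count. Of 5 classes of genes by expression, the highest held 37.0% of labelled WT regions and 19.8% of labelled Hira KO regions. Within classes of expression the pooled odds ratios (labelled Hira KO over labelled WT regions) were 0.0128 (erythroid), 0.0826 (G2 and mitosis), 0.146 (S-phase), 0 (heat shock) and 0.0440 (ribosomal). Their adjusted p by the Mantel-Haenszel test ran from 1.1e-21 to 0.00161. Without these classes the odds ratios were 0.0108, 0.0314, 0.105, 0 and 0.0251 in the same order. Regions are not replicates, so these p-values describe the peak lists.

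Hira was lower in both libraries labelled WT. A single mislabelled library of the 4 cannot be told apart: 0 correlated best with a library of the other group, but labelled Hira KO replicate 1 had 0.938 with its own group and 0.934 with the other, a margin within the SD of the correlations between groups (0.0234). Exchanged titles would predict a positive Hira fold change, but that is the observation itself, so it cannot decide the question. The log2 value of 0.50 had a 95% interval above 0, at an adjusted p by edgeR of 0.180. Its unadjusted p was 0.0327 by edgeR, 0.0506 by DESeq2 and 0.501 by limma on log2(TPM + 1). Mean Hira was 16.8 CPM in labelled WT and 23.8 CPM in labelled Hira KO, so neither group lacked its transcripts. The direction did not turn with scaling: over 6 other scalings the lowest log2 fold change was 0.289, above the bound of 0.25 set beforehand. The 2 TPM scales gave the 2 lowest values, and they also add a pseudocount and use limma. A part of scaling in the size of the change therefore cannot be told apart. A biological rise of Hira counts from exons outside the deleted part was not tested.

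Immunoglobulin transcripts were higher in both libraries labelled Hira KO. RNA of B cells is argued against by the B cell list without immunoglobulins, whose median log2 fold change was -0.776 (upper quartile -0.21). RNA of plasma cells cannot be told apart, although a sort for lineage-negative, Kit-positive cells is meant to remove them and no table measures its purity. The median of 19 plasma cell genes was 0.118 with 5 above 1, which met the bound set beforehand against it, but that bound was not taken as deciding because members went both ways (Prdm1 2.32, Derl3 1.84, Mzb1 -1.27, Fkbp11 -1.72) and their upper quartile, 0.80, lay past it. Among immunoglobulin constant genes, Igha rose from 53.1 ± 22.4 to 340 ± 28.7 CPM and Ighg1 from 0.109 to 6.53 CPM, both past edgeR's threshold. Ighd went from 6.81 to 11.0 CPM and did not pass. Some variable genes differed between the labelled Hira KO libraries, such as Ighv1-5 (34.8 and 1.14 CPM) and Igkv12-89 (16.9 and 1.80). Others, such as Igkv14-126 (14.8 and 12.3), were alike in both. Transcription of these loci in LSK cells stays open and was not tested.

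HSC and immediate-early lists had medians above 0 and cell cycle lists below 0 in labelled Hira KO over labelled WT. Labelled Hira KO replicate 2 as the only source is argued against, since without it the medians were 0.739 (HSC), -0.523 (G2 and mitosis) and 1.58 (immediate-early), and a gene length trend is argued against by an HSC median of 0.899 with that trend removed. Of the 3 splits of the 4 libraries into pairs only 1, the labelled one, gave as many genes past edgeR's threshold (292, highest other 0). The other splits mix labelled WT and labelled Hira KO libraries on each side. Any difference between the labelled pairs, whatever its cause, then widens the spread within sides and lowers the calls. The splits therefore do not bear on the cause, and 3 are too few for a share under 0.05. The male-like sex of labelled WT replicate 2 as the only source is argued against too: without it the medians were 0.992 (HSC), -0.548 (G2 and mitosis) and 2.07 (immediate-early), past camera at the preset correlation, although with an estimated correlation none of these lists passed even with all 4 libraries (adjusted p = 0.485), and edgeR called 1 gene higher and 1 lower (3 and 1 without labelled WT replicate 1). Cell handling, a different share of HSC in the gate and a change within cells stay open, as untested.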
